A study of Gallus gallus with 6 samples.

How the data were processed

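Total RNA was extracted from 3 samples of induced epiblast and 3 samples of contralateral area opaca of chick embryos, 12 hours after grafting, and biotin-labelled cRNA was hybridized to Affymetrix arrays, per the labels' protocols. The repeats are numbered as biological repeats. Whether a sample holds tissue of 1 or several embryos, and whether equal numbers share hosts, is not given in the sources used here, so p-values measure the spread between these samples.

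The deposited table holds 1 intensity value per probe set and array on a linear scale, and the submitters' processing notes name MAS5, whose signal combines the matching and mismatching probes of a probe set. The version, the scaling target and the background settings are not given in the sources used here. The table has 37690 probe sets in 6 columns, 1 per array, and 0 further columns of sample values. Arrays had not been brought to a common level, since their medians ran from 7.5 to 18.35 units. For arrays, the signal over background takes the place of depth: the share of probe sets under 16 units was 47.9%, 62.8% and 58.9% in control samples 1 to 3 and 46.9%, 60.7% and 63.7% in induced samples 1 to 3. Detection calls were not used here. On a dim array more probe sets sit near the floor, which compresses fold changes of weakly expressed genes.

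From these values, log2(signal + 16) was computed, arrays were quantile normalized, and probe sets whose mean over the 6 arrays lay below the 40th percentile (4.5 on the log2 scale) were left out, which kept 22614. Fold changes are on the log2(signal + 16) scale and understate the change of weak genes. Quantile normalization gives every array the same distribution of values, so that a shift of most genes in one direction would be removed. Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with a trend of the variance on the level, group as the only term, moderated two-sided test), with Benjamini-Hochberg adjustment and a threshold of 0.05. A test of 1 gene by exact permutation of 3 against 3 arrays cannot give a p below 0.1, so that single genes rest on the variance model shared across probe sets.

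This departs from the plan in 1 point. The design fixed before the data were examined took the signals to be scaled already and so had no normalization between arrays, with quantile normalization among the settings to be tried beside it. The column medians contradicted this, and quantile normalization was made the reported setting before any test was run. The fit as first planned is reported beside it. Several further combinations of scaling and design were tried after seeing the data, and the closing section lists each of them.

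Probe sets were named from GEO's platform annotation. Of the 37690 probe sets, 27166 had 1 gene symbol, 177 had several and were not named, and 10347 had none. Of the symbols, 26851 were brought up to date by their Entrez number through a table of RefSeq genes of the assembly GRCg7b, used for names only. No coordinates are given, since no build is named for the array. A gene was represented by its probe set with the highest mean over all 6 arrays, with the p-value of the probe-set fit, adjusted over the 10138 genes kept of 13050 named. In 4704 genes more than 1 probe set was kept. For the 24 genes with the largest changes among those that passed, the values of other kept probe sets are given. Probe sets of kinds that can match several transcripts stand behind HHEX, MSX1, KRT7, MCM2, FDFT1, MSMO1, TF, HOMER2, NCAM1, CYP26C1, DNAJB9 and BTG2, possibly of different genes, and behind HESX1, LFNG, VIM, VEGFA, TBXT and VIP, of a gene or gene family. A few listed names match under another current symbol, among them SLC2A3 as SLC2A14 and a keratin as KRT13, and such members may be paralogs of the gene intended.

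The genes named in the text were fixed by a rule set before the data were examined: of the genes with an adjusted p under 0.05 and no overlap of the groups, the 12 with the largest rise and the 12 with the largest fall, without uncharacterised names; up to 4 members of each list, those with the lowest p; and SIX4, EYA1, EYA2, DLX5, FOXI3, SOX3, OTX2, ETV5, GATA2, GATA3, MSX1, PAX7, SOX2, TBXT, ZNF462, HOMER2, DLX6, IRX1 and TFAP2A, whatever their values. A further gene fixed in advance is not reported here. Members of small counts are named as well.

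The 23 gene lists were also written before the data were examined, from knowledge of chick embryology, with markers of other tissues that a dissection could hold (blood and endothelium, yolk sac endoderm, mesoderm, germ cells). Some members, among them EYA2, ETV5 and PNOC, were chosen partly from knowledge of work on placode induction that may include these samples. The direction of the preplacodal, epiblast and later placode lists is thus not fully independent evidence. Each was tested with limma's camera on the gene table (preset correlation 0.01, Benjamini-Hochberg over the lists), beside camera with a correlation estimated from the data and fry. Camera compares a list with the other genes, and its preset correlation gives small p-values where members vary together between samples. Genes that passed when adjusted over the list alone are given as such.

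The procedure was tested on simulated data with the real levels and independent errors. Of 50 probe sets changed by a log2 value of 1, 39 were recovered, and of 50 each at 1.5, 2 and 3, all 50. The changed ones were drawn only from the brighter probe sets kept, with the same spread on every array. These shares thus do not carry over to weaker genes or to arrays of uneven quality. In the real data IRX1 at 2.47 and OTX2 at 2.08 did not pass over all genes (limma adjusted p = 0.0945 and 0.0759). Of 204 calls 15 were false. Of simulated lists of 15 genes, 10 of 10 with every gene moved up by 0.6 were called and 0 of 10 unmoved ones. Since errors were drawn independently, this says nothing about lists whose genes vary together. Nor does it carry over to lists with smaller shifts or with members going both ways.

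Alternatives planned in advance were pseudocounts of 1 and 64, no filter, a filter at the 60th percentile or on the third highest value, no normalization, centring on the median, eBayes without trend or robust, array weights, the repeat number as a block, leaving out each array, other thresholds, other ways to choose a gene's probe set, and the other list tests. Brightness of the arrays (repeat 1 against the others) was taken as a technical difference that holds both groups. It was not a term of the reported fit and entered only in settings chosen after seeing the data.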

Results

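Gene expression was measured in chick epiblast that had been exposed to grafted head mesoderm. Lateral head mesoderm of stage HH6 embryos was placed in the area opaca, the extraembryonic rim of the blastoderm, of younger hosts at stage HH4-. After 12 hours the graft was taken off and the epiblast under it was collected, together with the area opaca of the opposite side as the control. The comparison asks which transcripts go up or down while the mesoderm induces progenitors of the sensory placodes, the ectodermal thickenings that form lens, nose, inner ear and cranial ganglia. RNA of 3 induced and 3 control samples, numbered as biological repeats, was hybridized to 1 Affymetrix array each, and 37690 probe sets were read per array. Median signals were 17.7, 7.7 and 9.6 units in control samples 1 to 3 and 18.35, 8.3 and 7.5 in induced samples 1 to 3. Both arrays of repeat 1 were thus the brightest, with a mean signal 2.22 times that of the other 4 after trimming, and 46.9% to 63.7% of the probe sets of an array lay under 16 units. Signals were brought to a common distribution, and values below are log2(signal + 16) after that step. Profiles correlated across probe sets at 0.965 to 0.976 between control arrays, 0.973 to 0.981 between induced arrays and 0.951 to 0.982 between the groups. The number of arrays limits the precision of each value.

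Among the genes that passed over all genes tested, the largest rises in the induced epiblast were those of the homeobox transcription factors TLX1 and ISL1. VEGFD, a vascular growth factor, and PNOC, the precursor of the neuropeptide nociceptin, followed. TLX1 went from 5.30 ± 0.50 in the controls to 8.40 ± 0.60 (SD, n = 3 each), a log2 fold change of 3.11 (SE 0.333, limma adjusted p = 0.00796). ISL1 rose from 6.57 ± 0.55 to 9.36 ± 0.33, by 2.79 (SE 0.279, adjusted p = 0.00796), and a second probe set of the gene gave 2.87. VEGFD rose by 2.76 (SE 0.267, adjusted p = 0.00796). PNOC rose by 2.76 (SE 0.332, adjusted p = 0.0115), and its other probe set gave 1.47. EYA2, a transcriptional co-factor of the preplacodal region, rose by 2.46 (SE 0.304, adjusted p = 0.0115). TAC1, the precursor of substance P, rose by 2.43 (SE 0.263, adjusted p = 0.00796). The cardiac homeobox gene NKX2-5 rose by 1.90 (SE 0.231, adjusted p = 0.0115), and SFRP1, a secreted Wnt inhibitor, by 1.70 (SE 0.248, adjusted p = 0.0233), against 1.53 in its other probe set. PKDCCA, CCDC3, PDLIM4 and TMEM100 rose by 1.56 to 2.59 with adjusted p of 0.0115 to 0.0456, and the 2 other probe sets of PDLIM4 gave 0.50 and 0.92. Of the 29 other settings PKDCCA was called in 10, PDLIM4 in 15, CCDC3 in 16 and SFRP1 in 19. PKDCCA lost its call with either pseudocount, with each other filter, with median centring and with the repeat number as a block, among others. PDLIM4 and SFRP1 also lost theirs with that block. The probe set of PNOC is of a kind shared by several transcripts of a gene or gene family. Signals of VEGFD and CCDC3 were under 16 units in all 3 controls, where the added 16 makes a fold change too small.

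Among the genes that passed over all genes tested, those with the largest fall were GSTA3, a glutathione transferase, and LMO2, a transcriptional co-factor of blood and endothelial precursors. GSTA3, measured by a probe set that can match related transcripts, went from 8.35 ± 0.75 to 5.93 ± 0.37 (SD, n = 3 each), a log2 fold change of -2.43 (SE 0.347, adjusted p = 0.021). LMO2 went from 7.86 ± 0.21 to 5.68 ± 0.62, a change of -2.18 (SE 0.296, adjusted p = 0.0162), against -0.75 in its other probe set. TAL1, a transcription factor of the blood lineage, changed by -1.74 (SE 0.203, adjusted p = 0.0112), and KDR, a receptor for vascular endothelial growth factor, by -1.84 (SE 0.216, adjusted p = 0.0112). Their other probe sets gave -0.17 and -0.25. The water channel gene AQP1 changed by -1.95 (SE 0.265, adjusted p = 0.0162). LGALS2, MAT1A, GPD1L2, AvBD10, ST3GAL5, FABP2 and PMP22 fell as well, with log2 fold changes of -2.10 to -1.22 and adjusted p of 0.0155 to 0.0481. PMP22 had -1.22, against -0.80 in its other probe set. PMP22 was called in 10 of the 29 other settings, MAT1A in 15 and LGALS2 in 16. With the repeat number as a block PMP22 and MAT1A lost their calls. The probe set of AvBD10, like that of GSTA3, can match related transcripts, and that of LGALS2 is of the same kind as that of PNOC. Signals of AvBD10, a defensin, and FABP2, a fatty acid binding protein, were under 16 units in all 3 induced samples.

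**Figure D1:**
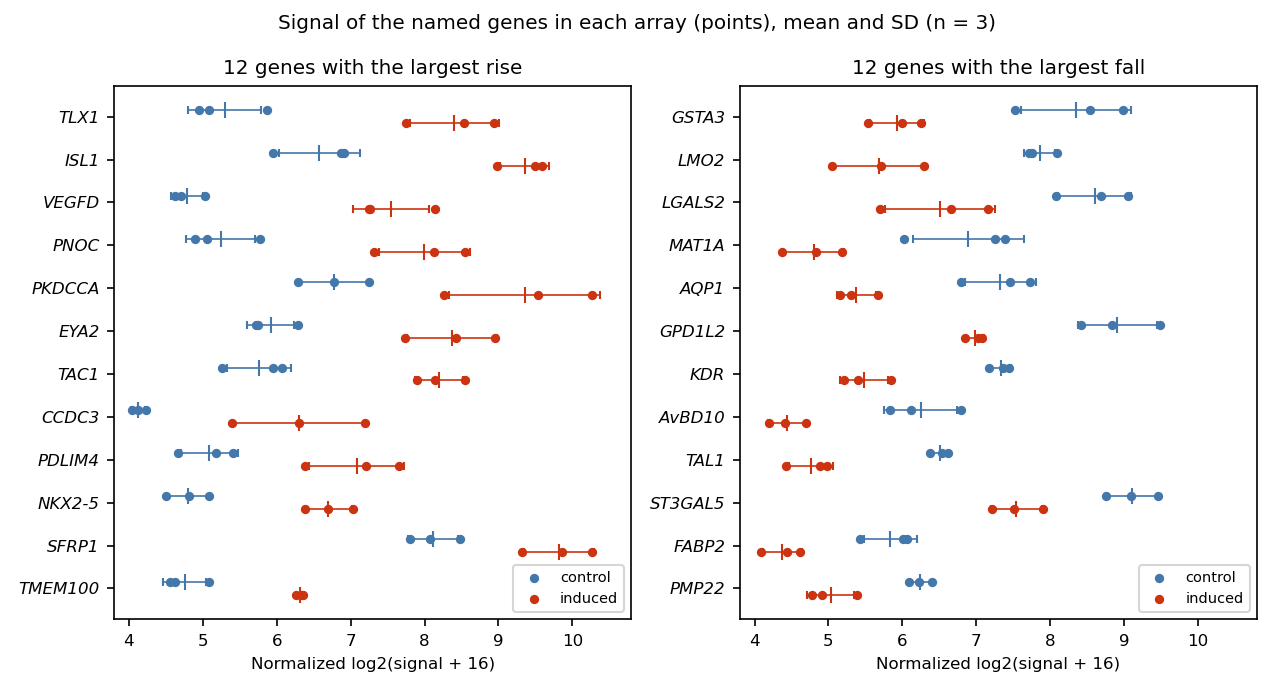
Normalized log2(signal + 16) of the 12 genes with the largest rise (left) and the 12 with the largest fall (right) on the x axis, with 1 point per array, a tick at the mean and a bar of 1 SD for the 3 control (blue) and 3 induced (red) samples. Only named genes with an adjusted p under 0.05 and no overlap of the groups were ranked. In each of these genes the 3 induced values lie on one side of the 3 control values, as that rule requires, for instance in TLX1 with a control mean of 5.30 and an induced mean of 8.40.

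Across the 10138 genes tested, 38 differed at an adjusted p under 0.05, of which 20 rose and 18 fell, and 1179 had an unadjusted p under 0.05. Over single probe sets, 22 of 22614 differed (15 higher, 7 lower, 2 of them without a gene symbol), and 2206 had an unadjusted p under 0.05. The induced and control values did not overlap in any of the 38 genes, nor in 1676 of all genes tested (16.5%, where chance gives 10%). The counts depended on single arrays: 120 genes passed without induced sample 3, 47 without control 1, 28 without control 2, 9 without control 3, 5 without induced 1 and 1 without induced 2. For probe sets these counts were 110, 35, 12, 10, 5 and 2. Of the 24 genes named above, 19, 15 and 7 passed without control 1, 2 and 3, and 5, 1 and 23 without induced 1, 2 and 3. VEGFD was the only one of the 24 that passed in all 6 of these runs, and PMP22 passed in 0. Across them the 12 risen genes had log2 fold changes of 1.40 to 3.41 and the 12 fallen ones of -2.79 to -1.10. Over all settings the ranges were 0.77 to 4.73 and -3.33 to -0.62, with the ends set by the added constant. With 64 in place of 16, TMEM100 had 0.77, NKX2-5 1.02, CCDC3 1.01 and PMP22 -0.62, and with 1, CCDC3 had 4.73, NKX2-5 2.87 and AvBD10 -3.33. With the mean of a gene's probe sets PDLIM4 had 1.14, KDR -1.05 and TAL1 -0.95. Without normalization between arrays, which was the fit planned before the data were examined, 9 genes passed (5 higher, 4 lower), 8 of them among the 38 and 8 among the 24 named, and 12 probe sets passed (7 higher, 5 lower). With the repeat number as a block on the values that were not normalized, 360 genes (113 higher, 247 lower) and 587 probe sets (188 higher, 399 lower) passed. In the 4 dimmer arrays alone 4 genes and 5 probe sets passed. The 24 named genes had the same sign there and in the pair of bright arrays, which the rule of no overlap between the groups had fixed in advance. Risen genes had log2 fold changes of 1.43 to 3.32 in the dimmer arrays and 1.80 to 2.77 in the bright pair, and fallen ones of -3.00 to -1.23 and -2.31 to -0.84. In the arrays of these risen and fallen genes, the blood and endothelium list described below averaged -0.95, -1.32 and -0.65 relative to the control mean in induced samples 1 to 3.

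Genes of the preplacodal region, the band of ectoderm from which the sensory placodes form, were higher as a group, with a median log2 fold change of 0.81 and all 8 measured genes above the controls (camera adjusted p = 8.76e-06, or adjusted p = 0.164 with an estimated correlation). EYA2, IRX1, DLX6 and HESX1 rose when adjusted over the list alone, and EYA2 also over all genes. DLX6 went from 4.99 ± 0.22 to 6.13 ± 0.55 (SD, n = 3 each), by 1.14 (SE 0.272). IRX1 rose by 2.47 (SE 0.529) and HESX1 by 1.23 (SE 0.442), and the adjusted p of DLX6, IRX1 and HESX1 over all genes was 0.13, 0.0945 and 0.321. HESX1 passed over the list in 1 of the 6 runs without an array, that without induced 3, and the other 3 in all 6. Over all genes 4 of the list passed without induced 3 and 0 without induced 1 or induced 2. EYA2 also lost that call without normalization between arrays, the fit planned before the data were examined, and in the 4 dimmer arrays, so that 0 of the list passed over all genes in either. Without normalization 7 of the 8 genes lay above the controls. The median was 0.51 with a pseudocount of 64 and 0.38 with no filter, where 9 of 10 measured genes lay above the controls. Of the members that did not pass, DLX5 had a log2 fold change of 0.20 (SE 0.0964) and TFAP2A of 0.48 (SE 0.217). No probe set carried the symbol of SIX4 or FOXI3, and EYA1 lay below the filter on signal, with at most 6.8 units on an array. The list's median was 0.91 in the pair of bright arrays and 0.76 in the dimmer ones. In the same arrays the blood and endothelium list averaged -0.95, -1.32 and -0.65 relative to the control mean in induced samples 1 to 3, and the yolk sac endoderm list -0.65, -1.09 and -0.81.

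Genes of the early epiblast and the pre-neural state were also higher as a group, with a median of 0.49 and all 11 measured genes above the controls (camera adjusted p = 7.71e-06, or adjusted p = 0.164 with an estimated correlation). ETV5, an effector of FGF signalling, OTX2, a transcription factor of the anterior embryo, and ETV4 rose when adjusted over the list alone, by 1.15 (SE 0.22), 2.08 (SE 0.414) and 0.68 (SE 0.213). None of the 11 passed over all genes by limma, where the adjusted p of ETV5 was 0.0654 and that of OTX2 0.0759. Over all genes 1 passed without control sample 1 and 2 without induced sample 3, and over the list alone 6 passed without induced sample 3. ETV4 was not called without control 2, control 3, induced 1 or induced 2, where 2, 3, 2 and 2 genes of the list passed. SOX3 had a log2 fold change of 0.49 (SE 0.195, adjusted p = 0.37) and MYCN of 0.78 (SE 0.287). The list's median was 0.42 in the bright pair and also 0.42 in the dimmer arrays. Beside this, the blood and endothelium list averaged -0.95, -1.32 and -0.65 in induced samples 1 to 3 and the yolk sac endoderm list -0.65, -1.09 and -0.81.

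Genes of later single placodes were higher with a median of 0.29 over 8 measured genes, 6 of them above the controls (camera adjusted p = 0.00166, or adjusted p = 0.27 with an estimated correlation). ISL1, PNOC and PAX2 rose when adjusted over the list alone, the first 2 also over all genes, and PAX2 by 0.60 (SE 0.163). PAX2, CRYBA1, PITX3, MAFA, CRYBB2 and NEUROG2 were weak in both groups. Their means were 4.30 to 4.90 in the controls and 4.52 to 5.13 in the induced samples. Their log2 fold changes ran from -0.25 to 0.60, while ISL1 and PNOC each had 2.8. The list thus says little about later placode genes other than ISL1 and PNOC. PNOC was put on this list partly from knowledge of work on placode induction, so that its direction is not independent evidence, and the same holds for EYA2 and ETV5 on the lists above. PAX2 was not called without control 3, induced 1, induced 2 or induced 3, where 2 genes of the list passed. Over all genes 1 passed without control 3 or induced 1 and 0 without induced 2. The list's median was 0.12 without induced 2 and 0.16 without control 3, and its call ended without a filter on signal (median 0.05, adjusted p = 0.131). The blood and yolk sac endoderm lists were lower in these arrays, with medians of -0.997 and -0.75. CRYBA1, a lens crystallin gene, had a log2 fold change of 0.35 (SE 0.174). Neural plate genes did not shift (7 measured, median 0.06, camera adjusted p = 0.751), and none passed over the list alone by limma, with ZEB2 at -1.13 (SE 0.379) and NCAM1 at 0.47 (SE 0.18) having the lowest p, followed by CYP26A1 at 1.31 and SOX1 at 0.24. Without control 2, 1 of them fell, and without induced 3, 1 rose. SOX2 lay below the filter with at most 0.7 units. NCAM1, SOX1, EMX2 and PAX6 were weak in both groups, with means of 4.38 to 4.79 in the controls and 4.44 to 4.85 in the induced samples. These lie near the filter at 4.5, so the neural plate list says little about genes this weak. For the neural plate border and neural crest list (16 measured, median 0.25) the camera adjusted p was 0.156. It was 0.014 without induced sample 3, 0.0375 with each array centred on its median and 3.68e-06 without normalization. GBX2, a homeobox gene, rose by 1.70 (SE 0.457) and MSX1 changed by -0.97 (SE 0.256) when adjusted over that list alone. Without control 1, control 3, induced 1 or induced 2 the list had 0 such genes, without control 2 it had 2 that rose and 3 that fell, and without induced 3 it had 4 and 2. TFAP2B at 0.86 and SNAI2 at -0.91 did not pass. PAX7 lay below the filter with at most 9.3 units. ZNF462 had a log2 fold change of 1.18 (SE 0.302, adjusted p = 0.155) and HOMER2, a synaptic scaffold gene, rose by 1.43 (SE 0.215, adjusted p = 0.0275). Both had been chosen in advance partly from knowledge of work on placode induction, so that their direction is not independent evidence.

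The non-neural and surface ectoderm list did not shift, with a median of -0.14 over 16 measured genes, 7 above and 9 below the controls (camera adjusted p = 0.295, and 0.0249 without induced sample 3). None of its genes passed over the list alone by limma, but 1 rose without control 1, 1 fell without control 2, and 6 fell and 1 rose without induced 3. The median was 0.04 where probe sets that can match several transcripts were left out. GATA3 had a log2 fold change of 0.89 (SE 0.259, adjusted p = 0.204 over all genes) and KRT13, a keratin whose probe set may measure a paralog, of -1.24 (SE 0.389, adjusted p = 0.237). KRT7, an epithelial keratin, had one of -0.32 (SE 0.106) and VGLL1 of -0.90 (SE 0.353). GATA2 lay below the filter with at most 7.7 units.

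Genes of blood and endothelium were lower as a group, with a median log2 fold change of -0.997 and 19 of 22 measured genes below the controls (camera adjusted p = 3.2e-14, or adjusted p = 0.175 with an estimated correlation). When adjusted over the list alone 16 fell, and TAL1, KDR and LMO2 fell also over all genes. HBZ, an embryonic globin gene, went from 6.47 ± 0.63 to 4.95 ± 0.25 (SD, n = 3 each), a change of -1.52 (SE 0.298, adjusted p = 0.0724 over all genes). RUNX1, a transcription factor of blood stem cells, and PTPRC, a white blood cell marker, both chosen after their values were seen, had log2 fold changes of 0.35 and 0.22 and did not pass. Of the list, 7 genes fell over all genes without induced sample 3, 2 without control 2, 1 without control 3, 1 without induced 1 and 0 without induced 2, and over the list alone 1 gene rose and 18 fell without induced 3. The list's median was -0.97 in the bright pair and -0.90 in the dimmer arrays.

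Genes of yolk sac endoderm and hypoblast, tissues that underlie the epiblast, were lower with a median of -0.75 and 20 of 22 measured genes below the controls (camera adjusted p = 3.75e-10, or adjusted p = 0.175 with an estimated correlation). When adjusted over the list alone 11 fell, against 7 without control sample 3 and 3 without induced sample 2, and none passed over all genes by limma, against 1 without control 2 and 1 without induced 3. TTR, the gene of the transport protein transthyretin, changed by -1.53 (SE 0.278, adjusted p = 0.0527 over all genes), HHEX by -1.43 (SE 0.255, adjusted p = 0.052) HNF4A by -1.04 (SE 0.261, adjusted p = 0.147) and GATA4 by -0.67 (SE 0.172, adjusted p = 0.153). TF, the gene of transferrin and the brightest of the list in the controls at 10.40, was chosen after its value was seen and had a log2 fold change of 0.0086 (SE 0.0996). The controls differed among themselves in this list, with means of -0.01, -0.49 and 0.50 relative to their common mean in samples 1 to 3. Its median was -0.66 in the bright pair and -0.68 in the dimmer arrays.

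The head and lateral mesoderm list, which covers the tissue of the graft, did not shift (15 measured, camera adjusted p = 0.79), and its median of -0.10 and mean of 0.20 differed in sign. Beside NKX2-5, LUM rose by 1.62 (SE 0.469) and SNAI1 changed by -0.65 (SE 0.193) when adjusted over the list alone, and both were not called without control 2, control 3, induced 1 or induced 2. Over all genes NKX2-5 was not called without induced 1 or induced 2. The median was 0.06 without induced 3. MESP1 had a log2 fold change of 0.38 (SE 0.158) and TBXT of 0.32 (SE 0.399, adjusted p = 0.844). The germ cell list did not shift either (8 measured, median 0.04, mean -0.07, camera adjusted p = 0.996). PIWIL1, a germline small RNA pathway gene, changed by -1.29 (SE 0.232), DND1 by 0.59 (SE 0.155) and KIT by 0.84 (SE 0.271), and these 3 passed over the list alone, while DAZL at -0.74 did not. PIWIL1 did so in all 6 runs without an array, DND1 in 5 (not without induced 3) and KIT in 2 (not without control 1, control 2, induced 1 or induced 2). The median of the list was -0.04 without control 1, -0.06 without control 2 and -0.000542 without induced 2.

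**Figure D2:**
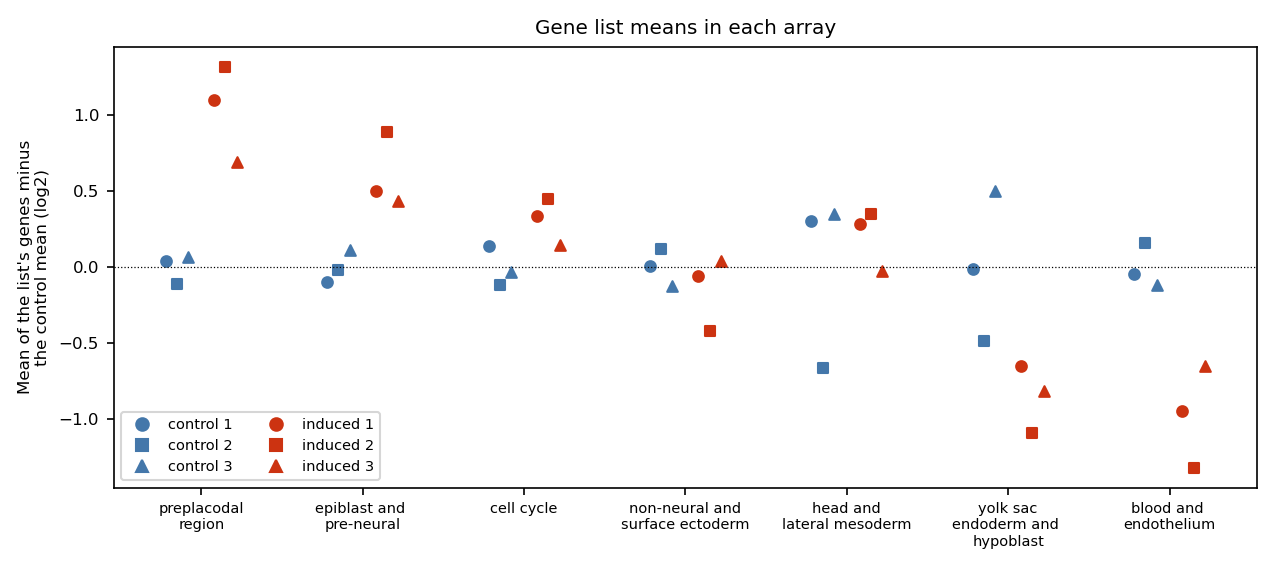
Mean over the measured genes of each of 7 gene lists, relative to the mean of the 3 controls (y axis, log2), for each control (blue) and induced (red) array, with a circle, square or triangle for repeats 1, 2 and 3. The preplacodal list lies at 1.10, 1.32 and 0.69 in induced samples 1 to 3 and the blood and endothelium list at -0.95, -1.32 and -0.65, while the head and lateral mesoderm list shows overlapping groups.

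Among signalling pathways, Wnt targets were lower with a median of -0.28, and 11 of 14 measured genes lay below the controls (camera adjusted p = 0.00491, or adjusted p = 0.175 with an estimated correlation). CDX4 and CDX2, homeobox genes of the posterior embryo, changed by -1.79 (SE 0.44) and -0.93 (SE 0.294), and AXIN2, a feedback inhibitor of the pathway, by -0.71 (SE 0.219), while SP8 rose by 2.08 (SE 0.695), each when adjusted over the list alone. SP8 kept that call in 1 of the 6 runs without an array, that without induced 3. Without an array the number that fell was 5 (induced 3), 2 (induced 1), 1 (control 1, control 2 or induced 2) or 0 (control 3). The list's call ended where probe sets that can match several transcripts were left out (adjusted p = 0.0619). Wnt antagonists were higher with a median of 0.29 over 11 measured genes (camera adjusted p = 0.0143, or adjusted p = 0.175 with an estimated correlation), and SFRP1, SHISA2 and SFRP2 rose over the list alone, the latter by 0.90 (SE 0.214) and 0.43 (SE 0.124), while KREMEN1 at -0.83 did not pass. That call ended without control sample 1 (adjusted p = 0.0781), without a filter (0.0892) and in the 4 dimmer arrays (0.0547). The median was 0.15 without induced 2, and 1 gene rose without control 3 or without induced 2. Antagonists of BMP and Nodal had a median of 0.31 over 7 measured genes (camera adjusted p = 0.0229, or adjusted p = 0.175 with an estimated correlation), with FSTL4 rising by 1.30 (SE 0.31) over the list alone, but not without control 2, control 3 or induced 2. FST, CHRD and BMPER, at 1.60, 0.31 and 0.38, did not pass. Their call held in 22 of 29 settings, with a highest adjusted p of 0.504 without a filter, and ended without control 1 (median 0.15, adjusted p = 0.218) and without induced 3 (adjusted p = 0.067). FGF and ERK targets had a median of 0.22 over 19 measured genes (camera adjusted p = 0.039, or adjusted p = 0.186 with an estimated correlation). ETV5, DUSP14 and ETV4 were higher and the immediate early gene EGR1 lower over the list alone, with log2 fold changes of 0.62 (SE 0.139) for DUSP14 and -1.06 (SE 0.272) for EGR1. The list was called in 18 of 29 settings. Without control 1, control 3, induced 1 or induced 2 its adjusted p was 0.0912, 0.0699, 0.109 and 0.275, and in the 4 dimmer arrays 0.182. The median was 0.14 without induced 2, 7 genes rose without induced 3 against 1 without induced 2, and EGR1 was not called without control 2 or induced 2. These 4 lists shifted in samples in which the blood and endothelium list (median -0.997) and the yolk sac endoderm list (median -0.75) were lower.

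BMP targets (19 measured, median -0.07, camera adjusted p = 0.735), the retinoic acid pathway (15 measured, median -0.21, mean 0.06, adjusted p = 0.735) and the Notch pathway (10 measured, median 0.03, adjusted p = 0.295, and 0.0444 without control 2) did not shift. Medians of the 3 lists turned their sign without some single arrays, BMP targets to 0.04 without induced 3, the retinoic acid list to 0.09 without control 1 and the Notch list to -0.08 without control 1. Over their lists alone ID1 rose by 0.60 (SE 0.176) and BMP2 changed by -0.89 (SE 0.195), as did MSX1 and GATA3 with the values above, CRABP1 changed by -0.76 (SE 0.198), and LFNG, a modifier of Notch receptors, rose by 0.93 (SE 0.201). STRA6 at 1.16, CYP26C1 at 1.33 and HOXB1 at -0.91 of the retinoic acid list did not pass, nor did HEY1 at 0.89, JAG1 at 0.43 and NOTCH1 at -0.27 of the Notch list. Without control 1 the calls of ID1, MSX1 and CRABP1 were lost, without control 2 those of MSX1 and GATA3, without control 3 those of ID1, GATA3 and CRABP1, without induced 1 those of ID1, BMP2, MSX1 and GATA3, without induced 2 all 6, and without induced 3 that of ID1. Calls were also gained. The retinoic acid list had 3 genes that fell without control 2, and 3 that rose and 2 that fell without induced 3. The Notch list had 2 that rose without control 3.

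Cell cycle genes were higher by a small amount, with a median of 0.33 and 25 of 26 measured genes above the controls, or 22 without normalization (camera adjusted p = 6.49e-07, or adjusted p = 0.209 with an estimated correlation). MCM2, a subunit of the replicative helicase, rose by 0.71 (SE 0.164) over the list alone, and 5 genes did so without control sample 1, 4 without induced sample 1 and 0 without control 2, control 3, induced 2 or induced 3. Against this the blood and endothelium list had a median of -0.997 and the yolk sac endoderm list of -0.75 in the same comparison. TPX2, BUB1B and RRM2 had log2 fold changes of 0.42 (SE 0.119), 0.39 (SE 0.119) and 0.33 (SE 0.103). Genes of cholesterol synthesis were lower with a median of -0.35 and 13 of 17 measured genes below the controls (camera adjusted p = 0.00011, or adjusted p = 0.175 with an estimated correlation). FDFT1, the enzyme that makes squalene, changed by -0.75 (SE 0.119, adjusted p = 0.0318 over all genes), MSMO1 by -0.83 (SE 0.166), STARD4 by -0.79 (SE 0.232) and SQLE by -0.54 (SE 0.161), and these 4 fell over the list alone, where 2 fell without control 2, without induced 1 or without induced 2. Over all genes 3 of the list fell without induced 3 and 0 without any other array. Blood and yolk sac endoderm genes were lower in the same induced samples, with medians of -0.997 and -0.75. Genes of the extracellular matrix and of epithelial to mesenchymal transition were lower with a median of -0.18, and 20 of 26 measured genes lay below the controls (camera adjusted p = 0.000275, or adjusted p = 0.175 with an estimated correlation). VIM, the gene of the intermediate filament vimentin, rose by 0.58 (SE 0.129) over that list alone, and 7 genes fell, among them TGFBI with -1.32 (SE 0.348), COL4A2 with -0.78 (SE 0.22) and ZEB1 with -0.70 (SE 0.2). Without induced sample 3, 4 of its genes fell, without control 1 it was 1, and without control 3, induced 1 or induced 2 it was 0. VIM was not called without control 3, induced 1 or induced 2, and the median was -0.45 without control 2. This list too was lower in samples in which the blood and yolk sac endoderm lists were lower (medians -0.997 and -0.75).

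Lists of dissociation and heat stress (19 measured, median 0.06, mean -0.03, camera adjusted p = 0.79), glycolysis and hypoxia (23 measured, median -0.01, mean 0.004, adjusted p = 0.709) and the interferon response (10 measured, median -0.03, adjusted p = 0.709) did not shift. CA9, a carbonic anhydrase, rose by 2.02 (SE 0.518) and SLC2A14, a glucose transporter, by 0.95 (SE 0.193) over the glycolysis list alone, where VEGFA changed by -0.81 (SE 0.217) and LDHA at -0.68 did not pass, and IFI6 changed by -0.99 (SE 0.256) over the interferon list alone. Without induced 2 all 4 calls were lost, without induced 1 those of CA9, VEGFA and IFI6, without control 3 those of VEGFA and IFI6, and without control 2 that of IFI6. Of the stress list none passed over the list alone by limma, but 1 fell without control 3, and its median was -0.05 without normalization. EGR1 had the lowest p in it, followed by JUN at -0.50 (SE 0.204), DNAJB9 at -0.33 and BTG2 at 0.35. ZNFX1, DDX60 and TLR3 of the interferon list had log2 fold changes of 0.25, 0.16 and 0.14.

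By camera with its preset correlation, 12 of the 23 lists shifted, 7 up and 5 down. With a correlation estimated from these 6 arrays none of the 12 kept an adjusted p under 0.05. Before adjustment over the lists, limma's camera gave 4 lists a p under 0.05 with it, of 0.00896 for the preplacodal list, 0.0143 for the epiblast list, 0.03 for the Wnt targets and 0.0336 for the blood and endothelium list. The estimate was 0.011 for the preplacodal list, 0.0112 for Wnt antagonists and 0.00986 for FGF targets, close to the preset 0.01. It was -0.0552 for Wnt targets and -0.0416 for BMP and Nodal antagonists. In these lists the larger p thus does not come from members varying together. Estimates for the other called lists ran from 0.0497 (epiblast) to 0.398 (later placodes). By fry, which asks whether the genes of a list move one way on balance, the preplacodal list and the Wnt targets passed, each with an adjusted p of 0.0395. Medians of other shifted lists also moved by over 1.5 times. A pseudocount of 64 gave 0.27 for the epiblast list, 0.11 for later placodes, -0.46 for yolk sac endoderm, -0.58 for blood, -0.15 for Wnt targets, 0.18 for Wnt antagonists and 0.12 for BMP and Nodal antagonists. A pseudocount of 1 gave 0.59 for later placodes, -1.29 for yolk sac endoderm, -0.48 for Wnt targets and 0.58 for BMP and Nodal antagonists, whose call ended there (adjusted p = 0.0677). With no filter the medians were -0.18 for Wnt targets, 0.14 for Wnt antagonists, 0.13 for BMP and Nodal antagonists, 0.11 for FGF targets (adjusted p = 0.0961) and -0.09 for the matrix list, and with a filter at the 60th percentile that of yolk sac endoderm was -1.37. In the 4 dimmer arrays BMP and Nodal antagonists had 0.14 (adjusted p = 0.113). Of the lists that did not shift, the border list turned to -0.03, the neural plate list to -0.05 and the germ cell list to -0.27 with the filter at the 60th percentile, and the retinoic acid list to 0.02 with no filter. In the dimmer arrays the retinoic acid list turned to 0.05, the mesoderm list to 0.02 and the Notch list to -0.07. Calls over the lists alone also depended on the settings, those of Wnt targets being 0 with a pseudocount of 1 or without the variance trend. With median centring 0 genes rose and 1 fell in the matrix list, and 0 genes passed in the border and glycolysis lists. Without normalization 0 genes passed in the lists of BMP targets, FGF targets, Notch, Wnt antagonists, cell cycle, cholesterol synthesis, matrix, germ cells, glycolysis and interferon. There 1 epiblast gene, 2 later placode genes, 3 border genes, 2 retinoic acid genes, 1 neural plate gene and 2 mesoderm genes rose, 1 Wnt target rose and 1 fell, and 10 blood genes fell. In the 4 dimmer arrays 0 genes passed in the lists of BMP targets, Wnt targets, border, retinoic acid and matrix. There 3 preplacodal genes, 2 epiblast genes, 2 FGF targets, 1 Wnt antagonist, 4 cell cycle genes and 1 mesoderm gene rose, 12 blood and 3 yolk sac genes fell, 2 germ cell genes fell, and 1 glycolysis gene rose and 2 fell. Over all genes NKX2-5, SFRP1, FDFT1, LMO2, KDR and TAL1 were not called without normalization nor in the dimmer arrays, where PNOC was not called either, and 1 other gene of the blood list fell without normalization.

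**Figure D3:**
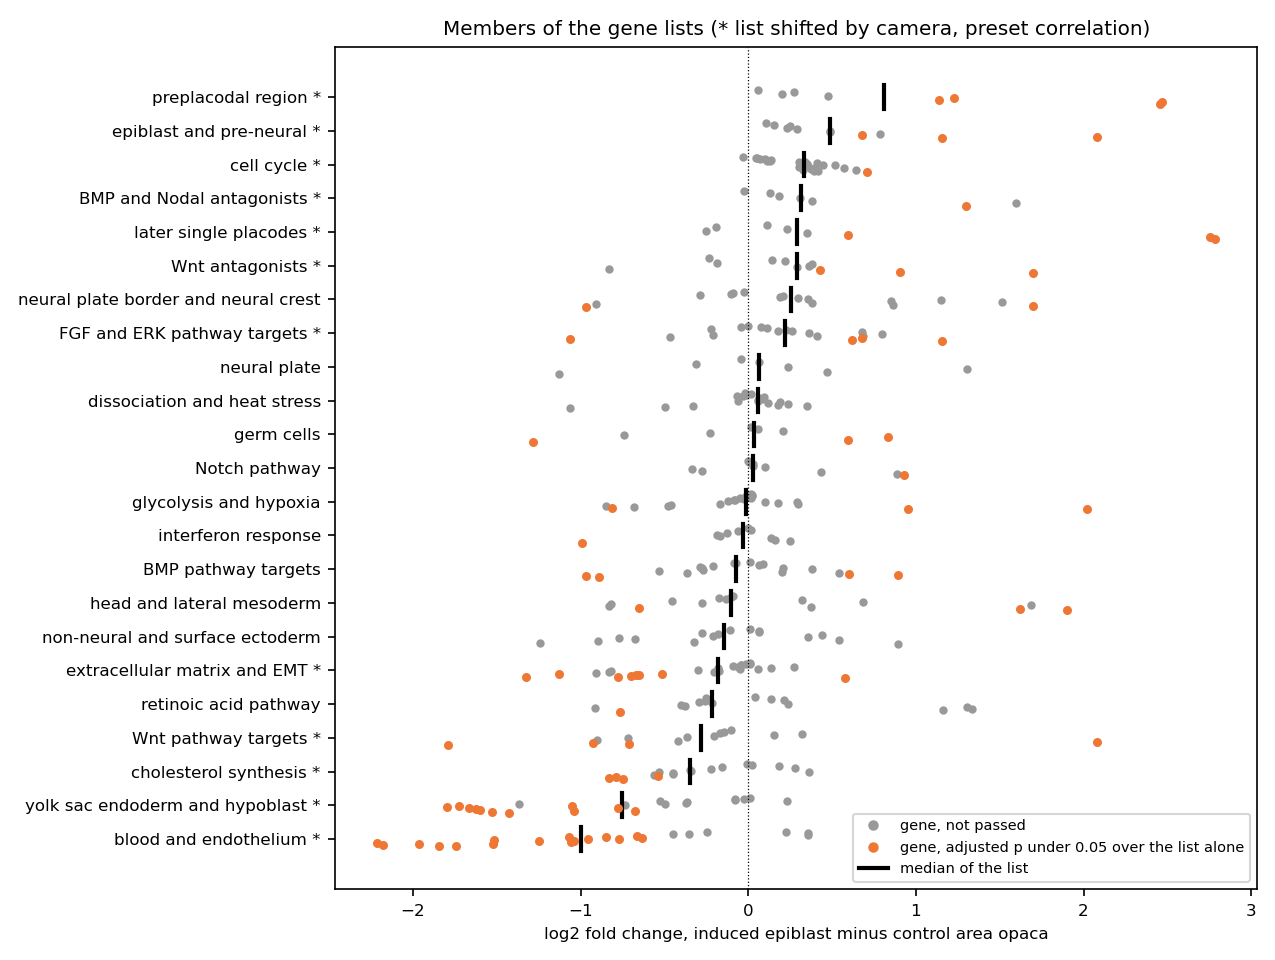
Log2 fold changes (x axis, induced epiblast minus control area opaca) of the measured genes of the 23 lists (y axis, ordered by median), with 1 point per gene, in orange where it passed over the list alone and in grey where it did not, and a black line at the list's median. An asterisk marks the 12 lists that shifted by camera with the preset correlation, from the blood and endothelium list at a median of -0.997 to the preplacodal list at 0.81.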

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

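The alternatives that scale by trimmed means, use array brightness as a term, keep only the 4 dimmer arrays, combine a scaling with a block or a brightness term, or refit the variance model on the gene table were chosen after seeing the data. No list that shifted and none of the 24 named genes turned its direction under the settings run, while the balance of higher and lower calls did turn in some. For the 24 genes the rule of no overlap between the groups left little room for a turn. Of 38 genes, leaving out 1 array gave 1 to 120, and of 22 probe sets 2 to 110, each with 5 arrays left. Without normalization 9 genes and 12 probe sets passed, and without the variance trend 21 genes. With array weights 143 genes and 86 probe sets passed, with brightness as a term 66 and 34, in the 4 dimmer arrays 4 and 5. Combined with the repeat number as a block, values without normalization gave 360 genes (113 higher, 247 lower, against 20 and 18) and 587 probe sets (188 and 399, against 15 and 7), and median centring 161 (68 and 93) and 144 (60 and 84). Combined with the brightness term, values without normalization gave 294 (86 and 208) and 430 (125 and 305), median centring 182 and 199 (100 and 99), and trimmed-mean scaling 68 and 34. For these changes, those without an array included, the cause was not tested. An adjusted p under 0.1 gave 103 genes and 72 probe sets, and an unadjusted p under 0.05 with at least 1.5-fold gave 646 (262 higher, 384 lower) and 1133 (482 higher, 651 lower), as looser thresholds do. A variance model refitted on the gene table gave 29 genes, all 29 among the 38, trimmed-mean scaling 43, and the remaining settings 26 to 50 genes and 17 to 31 probe sets. Of the 12 lists, 0 passed with an estimated correlation and 2 by fry, and 8 to 13 in the other settings. With an estimated correlation the preplacodal median of 0.81 had an adjusted p of 0.164, the epiblast median of 0.49 one of 0.164, and the yolk sac endoderm median of -0.75 and the blood median of -0.997 each one of 0.175. By fry the last 3 had an adjusted p of 0.0513, 0.101 and 0.0513, while under the 29 settings of camera with the preset correlation the preplacodal, epiblast, yolk sac, blood, cell cycle, cholesterol and matrix lists were called in all 29. Wnt targets were called in 28 of 29, later placodes in 27 of 28, Wnt antagonists in 26, BMP and Nodal antagonists in 22 and FGF targets in 18 of 29. Robust eBayes and the variance model refitted on the gene table are among the 29. They do not enter camera, so that neither could change the call of a list. Deviations of equally numbered arrays from their group means correlated at 0.55, -0.15 and 0.069 for repeats 1 to 3, and 2 of the 6 samples correlated best with their own number, so that the numbers were not taken to pair the samples. Those 2 were the bright arrays of repeat 1, whose profiles correlated at 0.982, and the fit with group as the only term leaves what they share in the spread. The axis of largest variation across arrays (40.7%) did not separate the groups, with induced 3 at 7.72 between control 1 at -5.32 and control 3 at 18.8. With the replicate block on normalized values 48 genes (21 higher, 27 lower, 29 of them among the 38), 26 probe sets (13 higher, 13 lower) and 11 lists passed, without the FGF targets (adjusted p = 0.0705). Trimmed-mean scaling with the block gave 48 genes and 28 probe sets (15 higher, 13 lower). The median log2 fold change of all genes was 0.016 as reported, -0.042 without normalization, 0.0069 with median centring and 0.021 with trimmed-mean scaling. Signal over background limits the weakest genes, since 46.9% to 63.7% of the probe sets of an array lay under 16 units.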

Other observations

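The tests of blood, endoderm and ectoderm shares and of head mesoderm were chosen only after the results they bear on had been seen, while the HOX, neuropeptide and heart lists were written before their values were looked at. The test of the heart list with NKX2-5 and over its weak members was likewise chosen afterwards.

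Among genes that passed over all genes but lie outside the rule for naming, and so were chosen after their values were seen, HOXB8 had a log2 fold change of -1.20 (limma adjusted p = 0.0318), IRX2, a homeobox gene of the family of IRX1, of 1.53 (adjusted p = 0.0208), GHRH, the precursor of growth hormone releasing hormone, of 1.45 (adjusted p = 0.0115), and VIP, another peptide precursor, of -0.94 (adjusted p = 0.0457). Signals of HOXB8 and VIP were under 16 units in all 3 induced samples. Together with the lower CDX4, HOXB8 led to the hypothesis that HOX genes, which pattern the trunk, are lower as a family in the induced epiblast. HOXB1 (-0.91) and HOXA2 (-0.26), whose values had been seen with the retinoic acid list, were left out of its test. The 11 other measured HOX genes all lay below the controls, with a median of -0.65 (95% bootstrap interval -0.80 to -0.28), and shifted by camera (p = 3.7e-07), but with an estimated correlation the p was 0.052, by fry it was 0.037, and none passed singly by limma (lowest adjusted p = 0.11). Their median stayed negative without normalization (-0.72), with median centring (-0.67) and with trimmed-mean scaling (-0.65), with 11 of 11 lower each time, while in the 4 dimmer arrays it was -0.36 with 10 of 11 lower and with no filter -0.18 with 17 of 25 lower. It was -0.26 with a pseudocount of 64, -1.3 with a pseudocount of 1, and -1.4 over 3 genes with a filter at the 60th percentile. Leaving out control 3, induced 1 or induced 2 turned 2, 1 and 2 members higher, with medians of -0.52, -0.49 and -0.57. A family-wide difference would give such a shift. The blood and endothelium list (median -0.997) and the yolk sac endoderm list (median -0.75) were lower in the same samples. Whether a difference in the tissue dissected lies behind the HOX shift was not tested.

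TAC1, PNOC and GHRH, 3 neuropeptide precursors, were higher, which raised the hypothesis that peptide genes rise as a family. VIP, which was lower (-0.94, adjusted p = 0.0457), goes against it and was left out of the test because its value had been seen. A list of 12 other measured neuropeptide genes gave a camera p of 0.49 and a median of -0.064 (-0.15 to 0.023), with 4 higher and 8 lower, and the lowest adjusted p among them was 0.79. Their median was 0.062 without control 1 and 0.029 in the 4 dimmer arrays. A rise across the family was thus not seen.

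The lower blood, endothelial and yolk sac endoderm genes may reflect how much of those tissues came along with each dissected piece. Their lists hold 22 measured genes each, 0 of them in another list, and the area opaca itself contains both tissues. Of the brightest members in the controls, chosen after their values were seen, CDH5 (9.90) and TTR (10.37) had log2 fold changes of -1.52 and -1.53, but TF, brighter still at 10.40, had 0.0086, which a lower share of its cells alone would not leave in place unless other cells express it. If cell shares vary between dissections, members should go up and down together within a group, and the correlation within groups was 0.318 for the blood list and 0.367 for the endoderm list, above all 1000 random lists matched on level (95th percentiles 0.0813 and 0.0711). The later placode list had 0.398 and the cell cycle list 0.276, so such a correlation is not particular to lists of a cell type. It cannot tell a varying share from other causes of joint variation. A varying share stays open for both lists, and so does a response of those cells or of the epiblast to the graft, which the design confounds with it.

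The rise of genes such as TLX1, ISL1 and EYA2 could come from a purer ectoderm, or from graft cells left behind. A purer ectoderm as the whole source of these rises is argued against only under 2 conditions. The ectoderm genes must not themselves respond to the graft, and the tissues that were lower must not express them. Neither condition was tested. The median of the non-neural and surface ectoderm list was -0.14 (-0.444 to 0.0901), where the risen genes, selected because they passed, had a median of 1.82. A smaller gain in purity stays open, since it would move these genes little. The heart-forming mesoderm list, which left out the risen NKX2-5 (1.90), had a median of -0.32 (-0.66 to 0.18) with 6 genes higher and 11 lower, or -0.18 without induced 2, -0.21 with a pseudocount of 64 and -0.15 with no filter. That upper bound lay under the 0.5 set in advance, but members bright in the controls would hide a small share. The 9 weak ones, NKX2-5 included, had a median of 0.18 (-0.66 to 0.90), with 5 higher and 4 lower. In the whole list IRX4 had 1.46, CSRP3 0.90 and ACTN2 0.54, while MYL4 had -1, ACTC1 -0.745 and TNNT2 -0.701. The interval of the weak members is too wide to decide, so that a small share of heart mesoderm stays open. Head mesoderm cannot be told apart from induction, the difference that the design names and which stays open, since its list without NKX2-5 had a median of -0.12 (-0.455 to 0.377) with members going both ways, and the 6 members weak enough in the controls to show a small share had a median of 0.094 with an interval of -0.22 to 1.

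The 6 arrays can be split into 3 and 3 in 10 ways, too few for a share under 0.05. As many genes, probe sets or lists as in the real split were found in 1 of the 10, the real split itself, with 38 genes against at most 0 in the others, 22 probe sets against at most 0, and 12 lists against at most 9.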
